A study of Homo sapiens with 21 samples.

How the data were processed

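Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured where heat shock factor 1 (HSF1), the main transcription factor of the heat shock response, and RNA polymerase II lay on the genome of MCF7 breast cancer cells and M0-91 acute myelogenous leukemia cells. Of the 21 samples, 11 were HSF1 libraries, 4 were RNA polymerase II libraries and 6 were IgG control libraries. Per the deposited summary table, every treatment lasted 6 hours. Groups and replicate numbers were taken from the sample titles. No label says whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

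The authors deposited 1 list for each of the 15 HSF1 and RNA polymerase II libraries, and the lists were made library by library with no pooling. Each row pairs a RefSeq transcript with 1 enriched region overlapping it or lying within 8000 bp of it, per the file headers and values. A transcript that has several regions therefore shows only 1 of them, and a region missing from a list can be hidden behind another region of the same transcript. Per the file headers, each region has a start and an end, the position of its highest bin, a peak height, a summed target signal and a summed IgG signal. The deposited heights and sums are signal values, the pileup of reads in 10 bp bins, with no normalization of the target. The deposited IgG signal equals whole reads multiplied by the ratio of target to IgG totals in 100% of the rows of each list, to within 0.05. The distance between transcript and region was deposited in base pairs, as a signed score that is 0 on overlap and negative upstream. The deposited summary table gives counts for each library, namely the total target reads, the total IgG reads, the height threshold, the number of enriched regions and the number of bound RefSeq transcripts. The lowest height in each list equals that threshold. For the 20 nM 27A replicate 2 library that table gives 1344 bound transcripts while the list holds 1724, a mismatch seen in this library alone. Coordinates are in hg18, per the submitters' processing notes. The aligner and the region caller are not given in the sources used here.

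Target totals ran from 3213457 to 18216083 reads. The list threshold corresponded to between 0.988 and 3.42 RPM. Depth thus differed between groups, and a region under its list's threshold was counted as not listed, never as absent. Heights were divided by the library's total target reads and given as RPM (the usual reads-per-million scale). These are values per library with no interval, because pileups are not independent counts. The main analysis used no other per-library normalization. Quantile, median and cyclic loess scaling were tried for RNA polymerase II as other settings. No spike-in is named in the labels.

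Transcripts were matched to genes with a RefSeq table on GRCh38.p14, used for names only. Of 19465 transcripts, 18659 matched by accession and 724 by symbol, and 82 remained unmatched. A total of 22 symbols that had turned into dates were recovered from their accessions. Reads shared by near-identical genes (HSPA1A and HSPA1B, UBB and UBC, histone and ribosomal protein genes) cannot be told apart here, and neighbours that share a promoter share a region.

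Regions were called shared when they had at least 1 bp in common. DMSO regions of MCF7 were those of replicate 1 that overlapped a region of replicate 2, while M0-91 had 1 DMSO library. Each DMSO region was then looked up in every treated list and recorded as listed, as not listed, or as listed elsewhere where the treated list attached the same transcript to another region. Numbers of regions were compared with an exact two-sided permutation test of 2 against 2 values, for which the smallest possible p is 0.333. Overlap between the cell lines was set beside 200 circular shifts of the MCF7 regions along their chromosomes. A total of 15 gene lists, fixed before the data were examined, were tested with Fisher's exact test, two-sided, against 19443 protein-coding genes, with Benjamini-Hochberg adjustment over the lists. Genes are not replicates, so these tests describe the lists of genes.

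For RNA polymerase II a gene was measured where all 4 lists gave 1 of its transcripts regions with at least 1 bp in common and where each library's highest bin lay in the shared stretch. This held for 10477 of the 16593 transcripts found in all 4 lists. Genes with a mean height under 2 RPM were left out. limma was run on log2(RPM + 0.1), with moderated statistics and Benjamini-Hochberg adjustment at 0.05, so fold changes are on the log2(value + pseudocount) scale. The same model was run on HSF1 heights at the MCF7 regions listed in all 4 libraries, a comparison added after the data were examined. Gene lists were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry. On simulated RNA polymerase II heights of 7823 genes with 200 changed, limma recovered 71% of the 100 genes changed by a log2 fold of 1. It recovered 93% of those changed by 2, with 2 false calls. The simulation held no shift common to all genes and no trend with height, so it does not bear on the number of calls in the real libraries. Overlap and exact tests returned the known answer in 9 of 9 simulated cases.

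The genes named were chosen by a rule written before the data were examined. For HSF1 it took the 10 highest regions under DMSO, up to 10 found in every DMSO library and every library of a treatment, and up to 5 found in every library of a treatment and in no DMSO library. For RNA polymerase II it took the 10 largest changes in each direction that passed the test and went the same way in both replicate numbers. It added up to 4 members of each list, and 10 heat shock genes in any case. Genes named outside it, among them regions whose transcripts had no DMSO listing, were chosen after their values were seen. Other settings tried were the upper part of each list by height, a larger shared stretch, midpoints within 1000 bp, lists of equal length, genes in place of regions, either DMSO library, the replicate number as a block, pseudocounts of 0.01 and 1, no filter, quantile, median and cyclic loess scaling, other backgrounds and each replicate left out. The analysis used Python 3.11.15, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.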

Results

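HSF1 occupancy was profiled in MCF7, an established breast cancer line, and in M0-91, an acute myelogenous leukemia line, to ask how inhibitors of protein synthesis change it. MCF7 cells received DMSO or 10 uM cycloheximide, an inhibitor of translation elongation, with 2 HSF1 libraries and 2 RNA polymerase II libraries for each. M0-91 cells received DMSO (1 HSF1 library), 27A at 20 nM, 27A at 100 nM or cycloheximide at 10 uM (2 HSF1 libraries each). The compound 27A is known here by its code name, and the series speaks of rocaglates. Each treatment had 1 IgG control in each cell line. MCF7 HSF1 libraries held 7515357 and 3213457 reads under DMSO and 16390954 and 13526571 under cycloheximide. RNA polymerase II libraries held between 12534728 and 18216083 reads. The M0-91 libraries held 11180969 reads under DMSO, 4963059 and 3300653 at 20 nM 27A, 6290127 and 7217736 at 100 nM, and 8898627 and 9637215 under cycloheximide.

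In MCF7 under DMSO the highest HSF1 peaks lay at heat shock genes. The highest (chromosome 2, 198072760 to 198073380) lay at the shared promoter of HSPD1 and HSPE1, which encode the mitochondrial chaperonin and its cochaperonin, and reached 69.8 ± 10.4 reads-per-million (RPM; SD, n = 2). HSP90AA1, encoding an HSP90 chaperone, reached 44.5 ± 4.91, USPL1 31.9 ± 6.77 and HSPH1, encoding an HSP110 chaperone, 28.8 ± 3.78. The other regions among the 10 highest were attached to UBB (a ubiquitin gene), BMP7, PGAM5 with PXMP2, CCT4 (a subunit of the TRiC chaperonin), ST13 with its neighbours, and HSPA8 (the constitutive HSP70). In 9 of these 10 the highest bin lay within 500 bp of the start site of an attached transcript, and BMP7 was the exception. The BMP7 region lies in the chromosome 20 window (45 to 60 Mb) described under the other observations. In DMSO replicate 1 the summed target signal was 40.4 times the scaled IgG signal at HSPD1 and 10.7 times at BMP7, the lowest of the 10.

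Under cycloheximide HSF1 height was lower at each of these regions that was still listed. The HSPD1 and HSPE1 peak went to 9.57 ± 3.09 RPM (SD, n = 2), 7.29-fold lower, and the HSPH1 peak to 5.33 ± 1.24, 5.39-fold lower. CCT4 was 8.80-fold lower and ST13 7.15-fold lower. HSP90AA1 stood at 7.24 in replicate 2 and was not listed in replicate 1, where the DMSO mean was 40.5 times the list threshold. USPL1 and HSPA8 likewise stood at 4.88 and 2.59 in replicate 2 alone, and UBB at 2.50 in replicate 1 alone. BMP7 and PGAM5 were in neither list, at DMSO heights 16.7 and 13.7 times the higher of the 2 thresholds. Next after HSPD1 and HSPH1, most of the regions that stayed highest in both cycloheximide libraries lay at chaperone genes, namely HSPA1B at 4.39 ± 1.21 against 15.1 ± 0.258, HSPA1A at 4.30 ± 1.86, DNAJB1 (an HSP40 cochaperone) at 3.93 ± 1.76 against 8.57, PTGES3 at 3.72 ± 1.12, FKBP4 at 3.01 ± 0.974 and HSP90AB1 at 2.52 ± 1.24. The region attached to FLJ37078 (chromosome 7, 75761890 to 75762270) stood among them at 3.71 ± 1.45, and the region of HSPB1, a small heat shock protein gene, lay beside it at 75770800 to 75771000. HSPA1A and HSPA1B are near-identical, so their separate values are uncertain. limma called all 21 regions listed in the 4 libraries lower, with a median log2 change of -2.35. To be listed, a region had to reach 3.42 RPM in DMSO replicate 2 but only 1.10 and 1.18 under cycloheximide. The 21 calls rest on the same 4 libraries, so they are not independent.

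**Figure D1:**
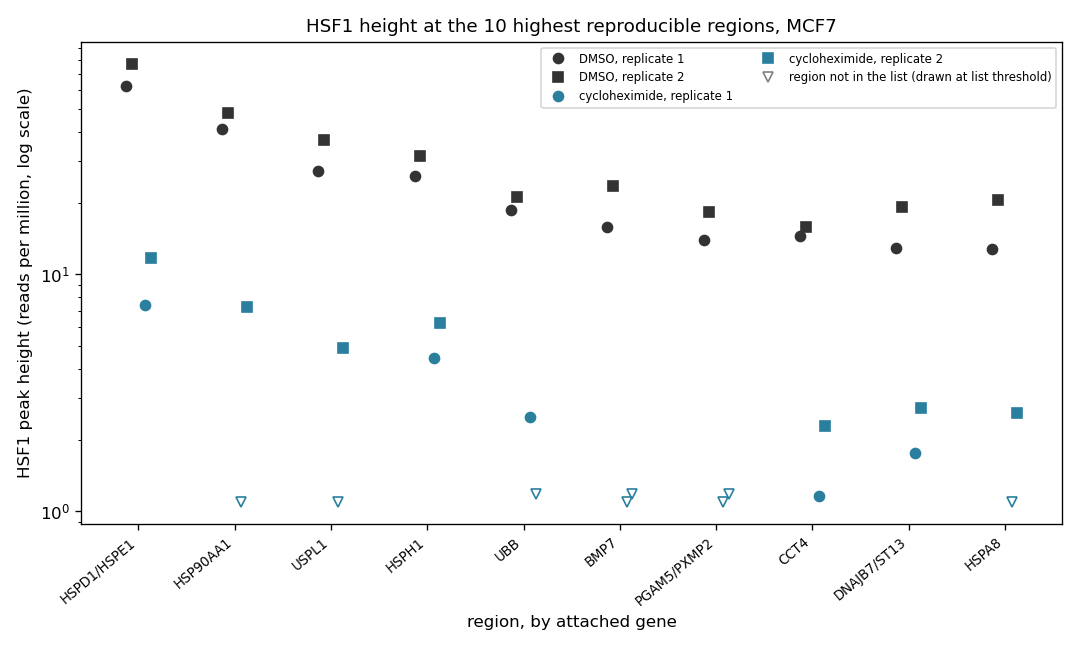
HSF1 peak height (RPM, log axis) at the 10 highest regions of MCF7, one point per library, with DMSO in black and cycloheximide in blue; circles are replicate 1, squares replicate 2, and open triangles mark a region missing from a list, drawn at that list's threshold. At HSPD1 and HSPE1 the DMSO libraries stood at 62.4 and 77.2 and the cycloheximide libraries at 7.38 and 11.8.

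Of the 161 DMSO regions found in both libraries, 22 were listed in cycloheximide replicate 1 and 63 in replicate 2, a mean of 26.4% ± 18.0 (SD, n = 2). In both lists together 21 regions were found, and in neither 97. The cycloheximide libraries were deeper and their thresholds lower (1.10 and 1.18 RPM, against 1.73 and 3.42 under DMSO). The totals the authors gave were 1194 and 661 regions under DMSO and 309 and 661 under cycloheximide, equal in replicate 2. Their means were 927.5 ± 377 and 485 ± 249 (SD, n = 2 each), with p = 0.667 by an exact two-sided permutation test. Distinct regions in the lists numbered 504 ± 202 and 201.5 ± 146 (SD, n = 2 each), with p = 0.333 by the same exact permutation test. As 0.333 is the smallest p possible with 2 against 2, this test could not tell the groups apart. The share kept rested on the reproducible set, since it was 8.11% when DMSO replicate 2 was left out and all 647 regions of replicate 1 were followed. Regions found in both cycloheximide libraries and in no DMSO library numbered 9, and 6 of these had a transcript that a DMSO list attached to another region. The other 3, at ZFAND2A, CRYM and FANCD2, stood between 1.32 and 1.80 RPM on average, near the thresholds.

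Among the regions listed in M0-91 under DMSO the same families stood highest. HSPD1 reached 67.97 RPM, HSP90AA1 57.2, HSPH1 56.9, ST13 56.7, TCP1 with MRPL18 51.8, HSPA8 45.8, HSPA1B 45.3, UBB 44.1, FKBP4 42.9 and CHORDC1 42.7. There is 1 DMSO library, so these values and the changes from them carry no replicate check or test. At 20 nM 27A all 10 regions were listed in both libraries. Heights averaged 102.9 ± 21.2 at HSPD1, 59.7 ± 17.2 at HSPH1, 60.8 ± 18.7 at ST13, 54.0 ± 12.9 at HSP90AA1 and 49.3 ± 4.62 at HSPA8 (SD, n = 2), near or above DMSO. UBB at 29.8 ± 7.44 was 1.48-fold lower than DMSO. HSPA1B at 21.0 ± 4.81 and CHORDC1 at 20.4 ± 9.59 were 2.16-fold and 2.09-fold lower than DMSO. Over a wider set most heights were lower than DMSO. Of the 222 DMSO regions at or above 6.67 RPM, 185 were listed in replicate 1 at a median log2 ratio to DMSO of -0.51 (167 lower) and 129 in replicate 2 at -0.96 (127 lower).

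At 100 nM 27A, 2 of the same 10 regions were listed in both libraries, each far below DMSO. HSPD1 stood at 4.97 ± 0.168 (13.7-fold below DMSO) and ST13 at 4.28 ± 0.212 (13.2-fold below). HSPA8 and TCP1 were listed in replicate 1 alone, at 3.50 and 2.07. The other 6 were in neither list, although 1 of them, HSP90AA1, had a transcript attached to another region in replicate 1. Cycloheximide left HSPD1 at 4.05 and 11.6 and TCP1 at 1.99 ± 0.269, 26.0-fold below DMSO, while 6 of the 10 were in neither list, HSP90AA1 and FKBP4 among them with a transcript attached elsewhere. HSPA1B and UBB were listed at 2.49 each in replicate 2 alone. DNAJB1 stood at 32.8 under DMSO, 16.3 and 15.8 at 20 nM, was in neither list at 100 nM, and stood at 2.58 in 1 of the cycloheximide libraries.

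**Figure D2:**
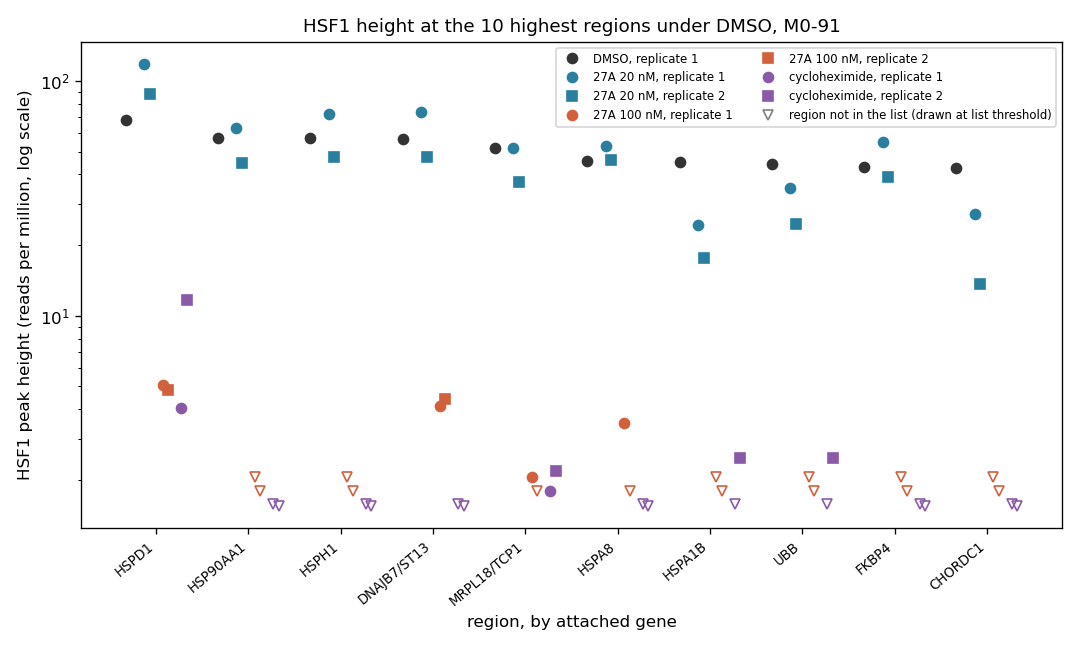
HSF1 peak height (RPM, log axis) at the 10 highest regions of M0-91 under DMSO, one point per library, with DMSO in black, 27A at 20 nM in blue, 27A at 100 nM in orange and cycloheximide in purple; circles are replicate 1, squares replicate 2, and open triangles mark a region missing from a list, drawn at that list's threshold. At HSPA8 the 20 nM libraries stood at 52.6 and 46.1 beside 45.8 under DMSO, and 1 library at 100 nM was listed, at 3.50.

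Over all 3996 regions of the M0-91 DMSO list, 8.02% ± 4.65 were found at 20 nM 27A, 0.425% ± 0.177 at 100 nM and 0.726% ± 0.566 under cycloheximide (SD, n = 2 each). Most of that list was weak, with a median height of 21 reads over a threshold of 15, and 58.7% of its regions held no IgG read (its IgG library had 4095856 reads). Of the 222 regions at or above 6.67 RPM, which is 2 times the highest threshold of the 7 libraries, 70.7% ± 17.8 were found at 20 nM, 3.83% ± 1.59 at 100 nM and 8.33% ± 4.14 under cycloheximide, a cut added after the data were examined. The authors' totals were 7560 regions under DMSO, 2621 ± 1269 at 20 nM, 363.5 ± 248 at 100 nM and 602.5 ± 55.9 under cycloheximide. The 20 nM mean is uncertain, because the total given for replicate 2, 1724, equals the number of rows in its list, which in the other libraries equals the number of bound transcripts instead. The 2 doses of 27A gave p = 0.333 by an exact two-sided permutation test for the number of regions and for the share found, the smallest p possible with 2 against 2. Regions in both 20 nM libraries and not in the DMSO list numbered 92, of which 66 had a transcript listed elsewhere under DMSO. The highest of the 66 were at USPL1 (90.7 ± 17.3 RPM, SD, n = 2), DNAJB6 (73.4 ± 21.6), MUM1 (45.9 ± 5.77), MAP2K2 (24.6 ± 12.5) and CCDC117 (22.9 ± 13.5). USPL1 and DNAJB6 stood above every height of the DMSO list. Strong DMSO regions may thus be hidden behind other regions of the same transcripts. Of the other 26 the highest, at ADCK5, stood at 8.98 ± 1.87. KIAA0664, PIK3CA, NLRP3 and DNAJB4 followed, between 6.20 and 7.21. At 100 nM the only such region with no DMSO listing of its transcript was at JMJD1A (2.67), and under cycloheximide there were 3, at ZCCHC3, LARS2 and RAD54B.

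Reproducible MCF7 regions were often bound in M0-91 as well. Of the 161 reproducible MCF7 regions, 106 (65.8%) overlapped a region of the M0-91 DMSO list, against a mean of 0.11 and at most 1 in 200 circular shifts. Both lists hold only regions at or near transcripts, and the shifts do not keep this. They therefore cannot show how much overlap nearness to genes alone would give. The observed share was between 32.8% and 35.7% with a DMSO replicate left out. In the other direction, 233 of the 3996 M0-91 regions (5.83%) were in at least 1 MCF7 DMSO list. Of the 50 highest M0-91 regions, 43 were in at least 1 MCF7 DMSO list. The highest regions lay near promoters in both lines: 37 of the 50 highest in MCF7 and 38 of the 50 highest in M0-91 were within 1000 bp of the start site of an attached transcript, against 39.6% and 45.8% of the rest.

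Protein folding genes were enriched among bound genes, although they were a minority of them (205 genes were bound in MCF7). In MCF7, 20 of 44 cytosolic chaperone genes were bound (odds ratio 86.5, Fisher's exact test, adjusted p = 2.4e-27), including HSPA8, HSP90AA1, DNAJB1 and HSPH1. Also bound were 4 of 14 TRiC and prefoldin genes (adjusted p = 5.5e-05), 3 of 15 mitochondrial chaperone and protease genes (adjusted p = 0.0018), 10 of 13 genes recalled as HSF1-bound in cancer cells (adjusted p = 2.8e-17), 3 of 37 proteasome and ubiquitin genes (adjusted p = 0.017) and 3 of 22 luminal breast markers, CA12, GREB1 and TACSTD1 (adjusted p = 0.0046), all by Fisher's exact test. No immediate-early, glycolysis, histone, p53 target, translation factor or haematopoietic gene of the lists was bound, 1 of 79 ribosomal protein genes and 1 of 23 endoplasmic reticulum stress genes were, and 2 of 33 cell cycle genes were (Fisher's exact test, adjusted p = 0.10). In M0-91, where the DMSO list reached 4790 genes, 30 of 44 cytosolic chaperones (adjusted p = 1.5e-08), 9 of 14 TRiC and prefoldin genes (adjusted p = 0.0066) and 12 of 13 recalled HSF1 targets (adjusted p = 3.3e-06) were bound by Fisher's exact test. So were 14 of 25 haematopoietic markers (adjusted p = 0.0034), 19 of 41 immediate-early genes (adjusted p = 0.0084), 12 of 24 glycolysis genes (adjusted p = 0.017) and 29 of 79 ribosomal protein genes (adjusted p = 0.037). With genes named in any of the lists as background, 3 lists of M0-91 remained enriched by Fisher's exact test in place of 7: cytosolic chaperones, recalled HSF1 targets and haematopoietic markers. In the upper part of the list by height 3 of these calls ended by Fisher's exact test. They were haematopoietic markers (4 of 25, odds ratio 1.31 beside 3.96, adjusted p = 0.63), immediate-early genes (1.93 beside 2.69, adjusted p = 0.16) and glycolysis genes (2.83 beside 3.11, adjusted p = 0.065). The glycolysis odds ratio thus stayed about as large. Proteasome and ubiquitin genes passed there (Fisher's exact test, adjusted p = 0.0056), while TRiC and prefoldin genes stayed enriched (Fisher's exact test, adjusted p = 4.7e-05).

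Cytosolic chaperone genes still had a listed region more often than other bound genes in MCF7 under cycloheximide and in M0-91 under both doses of 27A. The call held among higher regions at 20 nM alone. In MCF7 under cycloheximide, 17 of 20 bound cytosolic chaperones still had a region in at least 1 list, against 86 of all 205 bound genes (Fisher's exact test, adjusted p = 0.00080). All these genes were chosen for having a region listed under DMSO. DNAJB1, PTGES3, FKBP4 and CACYBP were among those kept, whereas AHSA1 (8.78 and 6.54 RPM under DMSO) and CHORDC1 were not. Among the upper part of bound genes by height the call ended, at 16 of 17 against 68.9% of 103 genes (adjusted p = 0.29, Fisher's exact test), while the odds ratio was 9.02 beside 9.53 for all bound genes. In M0-91 a gene counted as kept when at least 1 treated list attached it to any region, which need not be its DMSO region. Of the 3996 DMSO regions, 12.3% were found in at least 1 library at 20 nM, 0.801% at 100 nM and 1.23% under cycloheximide. At 20 nM 27A, 27 of 30 bound chaperones were kept against 38.6% of all bound genes (Fisher's exact test, adjusted p = 9.3e-08). All 12 recalled HSF1 targets were kept (Fisher's exact test, adjusted p = 8.0e-05). At 100 nM it was 7 of 30 chaperones (adjusted p = 0.031) and 6 of 12 recalled targets (adjusted p = 0.0012, Fisher's exact test) against 7.10% of bound genes, and among the upper part of bound genes by height only the recalled targets passed. In M0-91 under cycloheximide it was 6 of 30 chaperones (adjusted p = 0.33) and 7 of 12 recalled targets (adjusted p = 0.0013, Fisher's exact test) against 10.9%.

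RNA polymerase II stayed on most genes under cycloheximide. Over 7823 measured genes the median log2 change was -0.30, beside -2.35 for HSF1 at its 21 regions, a difference that was not tested. No height in any list exceeded 800 reads. limma called 3466 genes lower and 310 higher at this scaling, and 858 lower and 1205 higher after the medians were made equal, so single genes are best read against the median. The largest rises were at FOXQ1, a forkhead transcription factor gene (1.41 ± 0.0491 to 5.12 ± 0.361 RPM, SD, n = 2, log2 change 1.79, limma adjusted p = 8.7e-06), and TFPI2, a protease inhibitor gene (2.49 to 8.81, log2 change 1.78). GEM, AP3B2, SERPINB9, CPE, LIF (a cytokine gene), SERPINB1, BDKRB2 and ODC1 (the first enzyme of polyamine synthesis) followed, with log2 changes of 1.69, 1.64, 1.56, 1.51, 1.48, 1.41, 1.39 and 1.37. The largest falls were at TEAD2 (7.56 ± 0.492 to 1.78 ± 0.150, log2 change -2.03, limma adjusted p = 8.7e-06), SUMF1 (-1.90), CYP11A1 (-1.86), CRISPLD2 (-1.86), PYCR1, an enzyme of proline synthesis (-1.83), FADS1, a fatty acid desaturase (-1.80), LIMK1 (-1.76), MAP6 (-1.75), DUSP15 (-1.74) and NXN (-1.72).

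**Figure D3:**
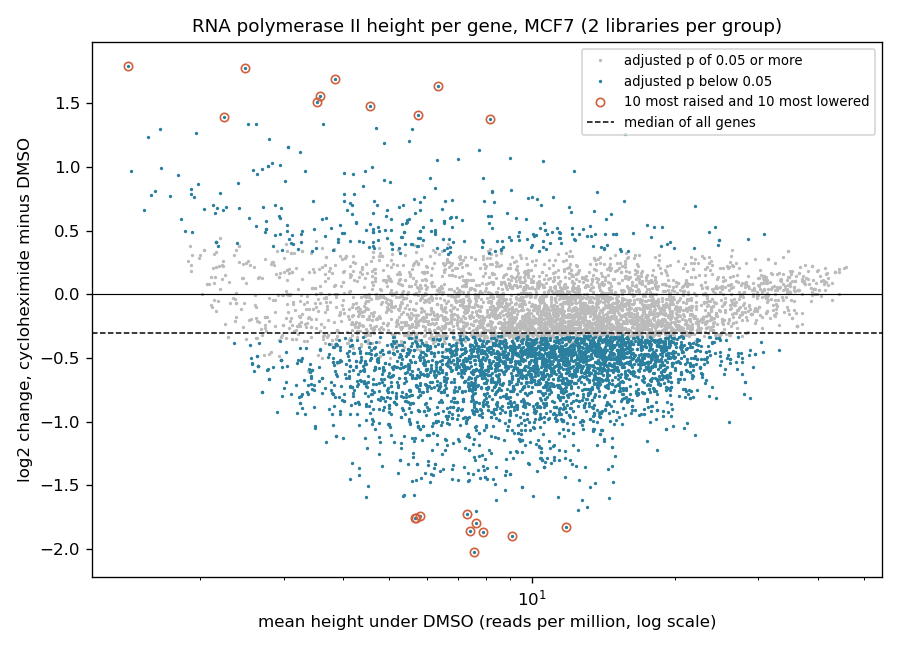
Log2 change of RNA polymerase II height under cycloheximide against the mean height under DMSO (RPM, log axis), one point per gene, with genes past the limma threshold in blue and the 20 genes of largest change ringed. The dashed line at -0.30 is the median of all 7823 genes.

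By listing alone, 220 genes had a region in both DMSO libraries and in neither cycloheximide library, and 173 the reverse, against 16 and 14 or 10 and 51 in the other splits of the 4 libraries. With lists cut to equal length the counts were 212 and 205, and in the upper part of each list 462 and 482, so the balance depends on the lists. BCAS1 (17.7 ± 2.85 RPM), CYP1A1 (8.08 ± 0.188) and OVOL2 (6.57 ± 0.260) were the highest listed under cycloheximide alone. BCAS1 lies in the chromosome 20 window (45 to 60 Mb) described under the other observations. FAM21C (5.51 ± 1.04) and ADA (5.10 ± 0.690) were among the highest listed under DMSO alone. The highest heights listed were 798 and 800 reads under DMSO and 799 and 797 under cycloheximide. Whether the lists left out higher regions is not given, so a gene missing from a list may also have stood above them.

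Some gene groups passed camera at its preset correlation, and none did with an estimated one. Immediate-early genes stood above the other genes (median log2 change 0.22, 21 measured, camera adjusted p = 1.3e-10, and adjusted p = 0.82 with an estimated correlation). Of these 4 rose and 1 fell by limma, with the same 4 and 1 adjusted over the list alone. CTGF went from 7.73 to 17.1 RPM (log2 change 1.13) and KLF2 rose by 0.59, while DUSP2 fell by 0.68. Luminal breast markers stood above the rest as well (median 0.07, 16 measured, camera adjusted p = 2.2e-05, and adjusted p = 0.82 with an estimated correlation), with 2 higher and 2 lower genes (2 and 1 adjusted over the list alone). MUC1 rose by 1.31 and PGR, the progesterone receptor, by 0.59. Replication-dependent histones (median 0.09, 28 measured, camera adjusted p = 1.1e-05), ribosomal proteins (median -0.07, 41 measured, camera adjusted p = 0.0016) and translation factors (median -0.09, 35 measured, camera adjusted p = 0.018) stood above the median of all genes, each with adjusted p = 0.82 with an estimated correlation. No histone gene passed the limma test, and 2 ribosomal protein genes did, both lower (0 adjusted over the list alone). EIF4A1, a translation initiation helicase gene, rose by 0.44 and 7 translation factor genes fell, EIF4G3 by 0.62 (1 and 5 adjusted over the list alone). Under cyclic loess scaling, which removes trends with height, only immediate-early genes kept a camera adjusted p under the threshold, at 0.0077. Under quantile scaling immediate-early genes and luminal markers kept it, with camera adjusted p-values of 0.0033 and 0.043.

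The other lists did not pass by camera. limma's fry, which tests whether a list moves on balance and does not compare it with other genes, called glycolysis (adjusted p = 0.0031), cell cycle, p53 target and proteasome genes (adjusted p = 0.033 each) and recalled HSF1 targets (adjusted p = 0.049) lower, as the median of all genes was. Of 26 cytosolic chaperones, 2 rose (DNAJB4 by 0.64 and DNAJA4 by 0.37) and 7 fell, with the same counts adjusted over the list alone, among them CRYAB (-0.91) and AHSA1 (-0.81), and with camera adjusted p = 0.69. Of 16 endoplasmic reticulum stress genes, ATF4 rose by 0.51 and 4 fell (also 1 and 4 adjusted over the list alone), with PDIA4 at -0.89 and HYOU1 at -0.70 (camera adjusted p = 0.38). Of 21 cell cycle genes 13 were lower (14 adjusted over the list alone), led by CDK2 (-1.39) and CCNE1 (-1.24), with camera adjusted p = 0.084. Of 9 p53 targets 6 were lower (6 adjusted over the list alone), with BBC3 at -1.28 and TP53INP1 at -1.21 (camera adjusted p = 0.69). Of 21 proteasome and ubiquitin genes 11 were lower (11 adjusted over the list alone), PSMC3 and PSMD3 among them at -0.89 and -0.79 (camera adjusted p = 0.74). Mitochondrial chaperones (5 of 13 lower), TRiC and prefoldin (2 of 9 lower), glycolysis (2 of 6 lower), recalled HSF1 targets (3 of 5 lower) and haematopoietic markers (none of 4 past the test) had camera adjusted p-values of 0.935, 0.686, 0.935, 0.935 and 0.0837. Adjusted over the list alone the counts of lower genes were the same, and 1 recalled HSF1 target passed as higher.

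Genes bound by HSF1 were not told apart from other genes in RNA polymerase II. The 103 measured genes had a median log2 change of -0.22, against -0.30 for the others, a difference of 0.09 (limma's camera, p = 0.515, and p = 0.854 with an estimated correlation), while limma's fry, with no comparison to other genes, found them lower on balance (p = 0.033). By limma 3 were higher and 30 lower (2 and 26 adjusted over the list alone). At HSPA8 RNA polymerase II went from 26.0 ± 0.895 to 19.3 ± 0.681 RPM (log2 change -0.43, limma adjusted p = 0.014). This call ended under median, quantile and cyclic loess scaling. It ended too when either DMSO replicate was left out, although the fall was about as large against either of them (25.4 and 26.7 RPM). HSP90AA1 stood at 38.96 ± 2.08 and 39.7 ± 5.73, HSPH1 at 26.3 ± 0.254 and 25.6 ± 2.29, DNAJB1 at 28.3 ± 1.93 and 25.2 ± 5.08, and HSPD1 at 23.1 ± 0.784 and 19.7 ± 1.11, with limma adjusted p-values of 0.908, 0.815, 0.338 and 0.152. The signs of the changes at HSPH1, DNAJB1 and HSPD1 turned under median scaling. That scaling shifts all genes of a library alike, so the turn says only that these falls were smaller than the common shift. The sign at HSP90AA1 turned under quantile scaling. The regions listed for RNA polymerase II averaged under the limit of 2 RPM at HSPA1A (1.68 and 1.92 under DMSO, 2.12 and 1.36 under cycloheximide). The same held at HSPA1B (1.74 and 1.43, then 1.66 and 1.28). Each transcript shows only 1 region, so higher signal at HSPA1A and HSPA1B may have gone unlisted. HSP90AB1, HSPE1 and HSF1 had no region with a common highest bin in all 4 lists. None of these genes was tested. The HSF1 gene itself had no HSF1 region in any MCF7 list.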

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

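Cyclic loess scaling, quantile and median scaling for gene lists, the 20 nM 27A height comparison, the limit to heights under 200 reads, the restriction to regions at 2 times the highest threshold, the removal of regions listed elsewhere, the looser match of RNA polymerase II regions, the HSF1 height comparison and the removal of 4 windows were chosen after the data were examined. No gene called by limma was called in the other direction under another scaling, but the median log2 change of RNA polymerase II went from -0.30 to 0.04 under median scaling, which makes the library medians equal, and the balance of calls turned. Of the results that answer a comparison, 127 recalculations stayed on their side or within the spread and 43 moved. These leave out the RNA polymerase II median under median, quantile and cyclic loess scaling, where it was 0.04, -0.009 and -0.003. For shares of HSF1 regions, staying meant within 1 SD of the 2 treated libraries, a wide spread. For single genes and regions, together with the counts of genes listed under 1 treatment alone, 425 stayed, 13 moved, 5 fell under the threshold and 1 passed it. The cause was not tested unless stated.

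The share of MCF7 DMSO regions found under cycloheximide (26.4%) ran from 8.11% to 39.1% with a replicate left out, was 6.86% for regions of either DMSO library and 54.3% for those at 2 times the highest threshold or more. For M0-91, the share at 20 nM 27A became 67.2% with lists of equal length, 13.6% with midpoints within 1000 bp, 24.2% for genes and 70.7% for the higher regions. In the same order the share at 100 nM became 4.10%, 1.39%, 3.77% and 3.83%, and that under cycloheximide 7.46%, 2.26%, 5.97% and 8.33%. The 2 doses of 27A kept their order in each of these. The log2 ratio of region numbers for M0-91 cycloheximide was -3.27 over distinct regions in place of -3.65. The share of MCF7 regions found in M0-91 was between 32.8% and 35.7% with a DMSO replicate left out, since all regions of 1 list then enter. HSF1 heights were called lower at between 19 and 58 regions with a replicate left out, of between 21 and 63 compared, in place of 21 of 21.

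With genes named in any list as background, 3 lists of M0-91 were enriched. Among kept genes, MCF7 had 0 lists in the upper part by height and between 1 and 2 with a replicate left out, 100 nM 27A had 1 in the upper part and between 1 and 2 with a replicate left out, and M0-91 cycloheximide had 3 where genes had to be kept in both libraries.

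RNA polymerase II genes called higher numbered 142 in the upper part of each list, 730 with quantile, 1205 with median and 805 with cyclic loess scaling, and between 161 and 493 with a replicate left out. Those called lower numbered 2060 with midpoints, 703, 858 and 721 under the same scalings, and between 1557 and 4107 with a replicate left out. Genes listed under DMSO alone and under cycloheximide alone numbered 462 and 482 in the upper part of each list, in place of 220 and 173. Of the replicates left out, DMSO replicate 1 left the fewest calls, and a lone library was then assumed to vary like the others. The median log2 change was -0.36 under 200 reads. By camera, 0 lists stood apart with an estimated correlation, 1 under cyclic loess, 2 under quantile scaling, 2 under 200 reads and between 4 and 6 with a replicate left out, in place of 5. The 5 lists called by fry were other lists than the 5 called by camera.

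Replicate numbers are shared between groups, but same-numbered RNA polymerase II libraries did not deviate together (r = -0.02 across genes, which are not independent). With the replicate number as a block, 309 genes were higher and 3429 lower and 21 HSF1 regions were lower, and each treated MCF7 library paired with its DMSO number gave 11.5% of regions and a log2 ratio of region numbers of -0.98. Of the 3776 genes called by the main fit 3620 were called with the block too, and the counts of gene lists and the labels of named genes stayed. No paired analysis was possible for M0-91 against DMSO because DMSO has 1 library. Thresholds between 0.988 and 3.42 RPM limit what can be called lost.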

Other observations

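The tests in this part, and the gene coverage count, were all chosen after the data were examined. Regions listed by RNA polymerase II covered at least 90% of 4 genes of 5000 bp or more in both cycloheximide libraries and under 50% in both DMSO libraries, out of 10574 genes. These were BHLHB2, CBX4, NAB2 and PHLDA1, covered at 100% under cycloheximide and at 0.707% and 6.19%, 12.3% and 12.3%, 36.4% and 39.4%, and 9.37% and 9.37% under DMSO. The reverse held for CDT1, a replication licensing gene, covered at 100% in both DMSO libraries and at 5.60% and 2.68% under cycloheximide. The other 2 splits of the 4 libraries gave 0 such genes in either direction.

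HSF1 lists differed in how many regions they shared with their replicate, with the fewest in M0-91 at 100 nM 27A and under cycloheximide. The DMSO lists of MCF7 had 161 regions in common, of 647 and 361. The lists of cycloheximide replicates in MCF7 had 34 regions in common, of 98 and 305, and those in M0-91 had 19, of 379 and 452. At 20 nM 27A it was 242, of 2214 and 936, and at 100 nM 5, of 390 and 134.

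Fewer HSF1 regions were listed after cycloheximide in both cell lines and after 100 nM 27A, although in MCF7 the authors' totals for replicate 2 were equal. Shallow or strict treated lists would leave at least 90% of the DMSO regions at 2 times the highest threshold in place. Instead 56.9% ± 27.5 of them were listed in MCF7, 3.98% ± 1.70 in M0-91 at 100 nM and 8.75% ± 4.30 under cycloheximide (SD, n = 2, regions listed elsewhere left out). This argues against depth as the whole cause. In MCF7 the cycloheximide lists also had the lower thresholds (1.10 and 1.18 RPM against 1.73 and 3.42 under DMSO), which argues against shallower or stricter treated lists there. Poor chromatin of the cycloheximide cells, if it lowered both targets alike, would lower RNA polymerase II in MCF7 about as far as HSF1. The median log2 change of RNA polymerase II was -0.30, which argues against a common loss of that size at the genes measured. Genes had to be listed in all 4 libraries to be measured, and whether both targets came from the same chromatin is not known. Poor chromatin that lowered HSF1 more than RNA polymerase II is therefore not excluded. A difference in HSF1 immunoprecipitation itself stays open, since no spike-in is named and M0-91 has 1 DMSO library, and so does a response of HSF1 to blocked protein synthesis, which is a hypothesis. For the shorter lists at 20 nM the corresponding share of 77.3% ± 19.5 (91.1% in replicate 1 and 63.5% in replicate 2) did not decide. The regions still listed had a mean median log2 height ratio to DMSO of -0.74 ± 0.32 when picked by DMSO height. When picked by the other 20 nM library it was -0.64 ± 0.45 (SD, n = 2). Both sets hold only regions of the DMSO list. Regions found at 20 nM but missing from that list, USPL1 and DNAJB6 among them, could not enter, which leans the ratios low. Heights at regions listed under DMSO were thus mostly lower, but the ratios cannot settle whether depth was the whole cause. The single DMSO library and immunoprecipitation leave the question open too.

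HSF1 regions of MCF7 clustered in 4 windows (chromosome 1, 110 to 120 Mb, chromosome 3, 60 to 65 Mb, chromosome 17, 50 to 65 Mb, and chromosome 20, 45 to 60 Mb), which held 51.0% and 25.2% of the regions under cycloheximide and 11.7% and 16.1% under DMSO, against 1.86% to 1.94% of RNA polymerase II regions and 0.746% to 2.17% of M0-91 regions. A candidate explanation is extra copies of these windows in MCF7. In the RNA polymerase II lists IgG reads per bin were between 3.31 and 4.23 times higher inside the windows than outside, which is consistent with it. In the HSF1 lists of MCF7 the ratio lay between 0.861 and 1.69, so the IgG signal of the HSF1 regions themselves does not show it evenly. No biological explanation was tested.

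RNA polymerase II height fell per library total under cycloheximide. Depth would leave the cycloheximide library whose total lies between those of the DMSO libraries unchanged, but its median log2 change was -0.32 against the nearer of them. Loss of reads near the highest listed height would spare lower regions, but regions under 200 reads had a median of -0.36. By height, the median ran from -0.41 between 50 and 100 reads to 0.11 between 600 and 800 (62 genes). Immunoprecipitation efficiency and less RNA polymerase II on genes both stay open, with no spike-in named.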
